A study of Mus musculus with 12 samples.

How the data were processed

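Poly(A) RNA was sequenced from livers of male C57BL/6N mice, 9 to 12 weeks old, in the postprandial state, 3 h after a meal that followed an overnight fast. Per the labels' protocols, a lysate freed of nuclei and debris by 3 low-speed spins was made from 1 g of liver, and the wrappER-associated mitochondria (WAM) fraction was prepared from that lysate. WAM are mitochondria recovered with the sheets of rough endoplasmic reticulum (ER) wrapped around them. Libraries were directional and made from 250 ng of RNA. There were 6 lysate and 6 WAM libraries.

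The deposited count table holds estimated counts per Ensembl gene, not normalised, for the 12 libraries, per the file headers. The submitters' processing notes name fastp 0.12.4, kallisto 0.44.0, DESeq2 1.20.0 and R 3.5.0 without giving a role to each; the genome build and annotation are not given in the sources used here. The authors' second table gives TPM, a length-scaled transcript abundance, per gene and library. Per the file headers, the authors divided WAM TPM by a mitochondrial content coefficient, which is the mean over the 13 mitochondrially encoded genes of the ratio of WAM TPM to lysate TPM in each mouse. Their enrichment is the ratio of coefficient-divided WAM TPM to lysate TPM in percent, averaged over mice. The authors' yes or no marks of protein localisation, per the file headers, were used for description only, and that use was chosen after their columns were seen. A further 60 columns of per-sample values were not used.

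The 48042 lines of the count table were reduced to 1 per gene, leaving 35498 genes, because genes with several protein accessions were repeated. Of the non-zero estimated counts, 32.5% were not whole, and all were rounded. Genes were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling and filterByExpr, which kept 11181 genes, 9570 of them protein coding. The kept genes held at least 99.7% of each library's counts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a 2-fold criterion was a log2 fold change of at least 1 in size. CPM values are library-scaled counts on the TMM scale, values are mean ± SD over 6 libraries, and SE is that of the log2 fold change. P-values of this gene test measure the spread between libraries of a fraction, and the 2 libraries of a mouse were treated as independent.

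Fixed before the data were examined were 36 gene lists, of which 32 had the minimum of 5 tested members. Of 1508 list symbols, 1495 were in the table and 1248 were tested. Lists were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Camera compares a list with the other genes, so its p-values rest on the spread across genes and the correlation used. Each list's percent of all counts was compared by a two-sided exact permutation test over all assignments of the 12 libraries, adjusted over the lists; the smallest p these assignments allow is 0.00217. The test was repeated with labels exchanged within mice, which allows 64 assignments and no p under 0.03125.

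Genes are named by a rule fixed in advance. It takes the 10 highest and 10 lowest log2 fold changes among called genes with at least 10 CPM and no overlap between groups, leaving out predicted genes. It also takes the 2 most abundant members and the largest change of each list, a set of genes always given, and the 5 highest ranked genes of the authors' list. Malat1, in that set, was not analysed here, and 5 genes that the rule names are not reported here; they were left out of the gap ratios but stay in other counts of named genes. Genes outside the rule are marked where they appear. Gene positions come from GENCODE M21 (GRCm38), matched by Ensembl identifier, and this build need not be the authors'.

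The count columns name a mouse and a fraction, so equal numbers mark the same mouse. As a check, deviations from the group mean correlated between lysate and WAM of the same mouse with r from 0.45 to 0.77, against at most 0.40 for other combinations, and each of the 6 WAM libraries correlated best with its own lysate. The mouse was not in the model, as fixed in advance, and a fit with the mouse as a block was run beside it. No 2 libraries of a group agreed within sampling noise, with chi-square per degree of freedom of at least 11.3. The biological coefficient of variation was 20.6% in lysates and 23.8% in WAM.

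The count test was run on counts simulated from lysate means and the spread of these libraries, with 200 of 11181 genes changed. It recovered 58.2% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold, with 5 false calls. As many genes were raised as lowered, libraries were not paired by mouse, and genes varied independently. In the real data most genes were called, and larger changes were mostly increases. Recovery and false calls under such changes were not tested. On a simulated list of 30 raised genes camera called the list, and it called 0 of 20 random lists. With genes varying independently, this cannot show how often camera calls lists of correlated genes. Splits of the real libraries with 3 WAM libraries in each group called 2 to 23 lists.

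Alternatives fixed in advance were DESeq2 size factors, library totals, TMM without mitochondrially encoded and the 10 most abundant genes, the authors' coefficient, other filters, DESeq2 1.42.0, limma on log2 TPM with pseudocounts of 1, 0.1 and 5, the mouse as a block, and leaving out each library. Chosen after seeing the data were median-centred limma, leaving out genes that share sequence with mitochondrial transcripts, removing a trend on transcript length, leaving out mouse 2 or mouse 5, the block with an estimated correlation, and the exchange of labels within mice. Transcript length was at first taken by mistake from the longest annotated transcript; it is now that of the transcript with the longest coding part, and both are reported. TMM centres fold changes near the typical mRNA (median log2 fold change -0.08), so higher and lower mean relative to that mRNA, not in amount per mitochondrion or per liver. Members of multigene families with near-identical sequence, such as the major urinary proteins, Ugt1a, Serpina1 and Cyp2c genes, are uncertain because reads can be split among them.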

Results

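Liver mRNA was compared between postnuclear lysates and the WAM fractions prepared from them, with 6 mice and 1 library of each kind per mouse. Total estimated counts ranged from 7400155 to 12023984 in lysates and from 8344144 to 9712382 in WAM libraries. The comparison asks which mRNAs travel with mitochondria and the rough ER wrapped around them.

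The 13 mRNAs encoded in mitochondrial DNA, which specify respiratory chain subunits, had the highest median of the 32 tested lists. They made up 2.69% ± 0.37 of counts in lysates and 17.9% ± 4.6 in WAM (SD, n = 6 each; two-sided exact permutation p = 0.00217, the smallest possible; adjusted p = 0.00354, and 0.0417 with labels exchanged within mice), and were higher in 6 of 6 mice. All 13 were called higher, with a median log2 fold change of 3.84 (camera adjusted p = 4.11e-11; adjusted p = 0.179 with an estimated correlation). mt-Co1 (ENSMUSG00000064351, mitochondrial chromosome, 5328 to 6872), a cytochrome c oxidase subunit, went from 4894 ± 1080 to 80075 ± 22678 CPM, a log2 fold change of 4.03 (SE 0.26, adjusted p = 4.74e-08). Of the 13, mt-Nd3, mt-Co3, mt-Nd1 and mt-Cytb followed at 3.88, 3.88, 3.87 and 3.87.

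**Figure D1:**
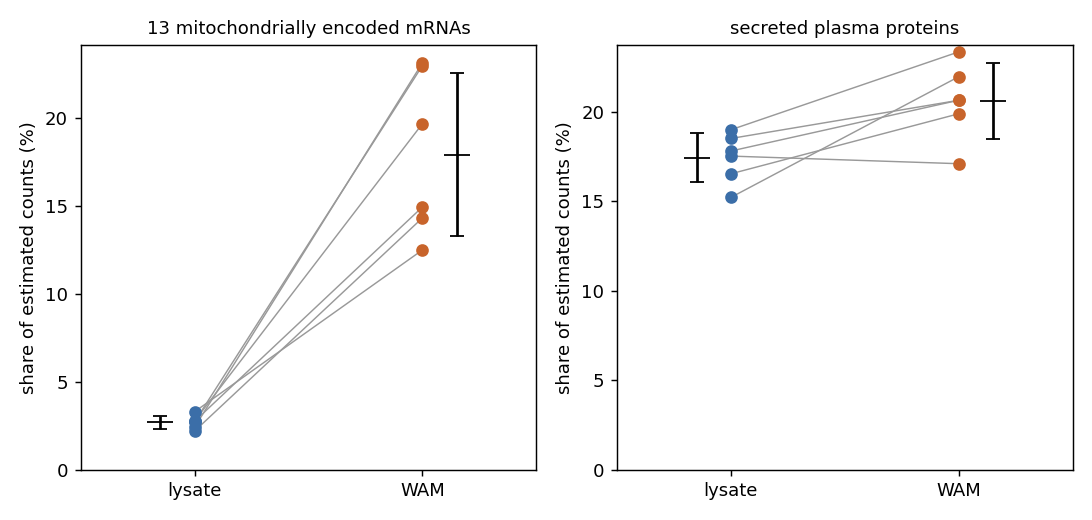
Percent of estimated counts (y axis) from mitochondrially encoded mRNAs (left) and from mRNAs of secreted plasma proteins (right) in lysate and WAM libraries. Each point is a library, lines join the libraries of a mouse, and bars beside the points are mean ± SD (n = 6); the mitochondrial share was 2.69% in lysates and 17.9% in WAM, and the secreted share 17.4% and 20.6%.

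Of 11181 tested genes, 6511 (58.2%) were called, 3293 higher and 3218 lower in WAM. Larger changes were mostly increases: 1790 genes were at least 2-fold higher and 71 at least 2-fold lower. The 71 was 188 without a filter on low counts, 33 with at least 5 TPM in lysates and 22 with median-centred limma, and rose more than 1.5 times without WAM library 5. With library totals the 2-fold counts were 27 higher and 6720 lower. The split between higher and lower rests on centring at the typical mRNA. For all called genes it was, scaled to library totals, 503 higher and 8652 lower, and with the authors' coefficient 6 and 11152. It was, with limma on TPM plus 1 56 and 9570 (plus 0.1, 55 and 9569; plus 5, 56 and 9565), and with median-centred limma 4130 and 2434. The median of all genes moved by -1.11 with library totals, -3.28 with the authors' coefficient, and -1.35, -1.52 and -0.97 with TPM plus 1, 0.1 and 5. Directions given here for gene groups are relative to that median. Without taking the shift off, library totals gave negative list medians for oxidative phosphorylation (-0.52), cytosolic ribosomal proteins (-0.58), mitochondrial ribosomal proteins (-0.81), mitochondrial import (-0.70), Slc25 carriers (-0.97), bile acid synthesis (-0.11) and fatty acid and triglyceride synthesis (-0.26), which are positive on the TMM scale, and a cholesterol synthesis median of -0.01. Among the fixed lists, camera called 19 higher and 3 lower, and 0 with an estimated correlation; 21 of 100 splits of the libraries, the real one included, gave at least as many called lists, but only 1 of the 38 with 3 WAM libraries in each group.

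**Figure D2:**
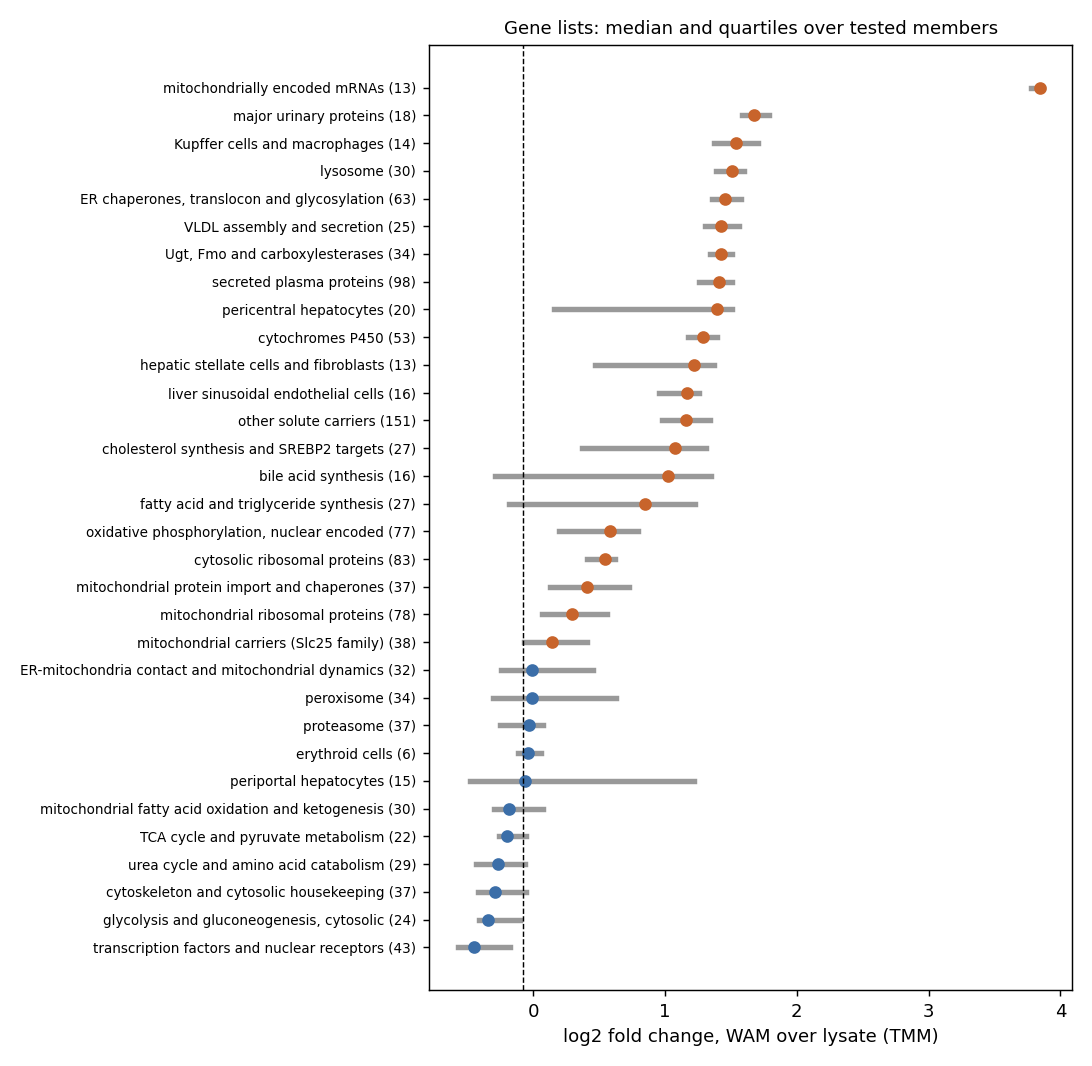
Median log2 fold change, WAM over lysate on the TMM scale (x axis), for the 32 tested gene lists (y axis, tested members in parentheses). Points are medians, orange above 0 and blue below, grey bars span the quartiles of the members, and the dashed line is the median of all tested genes (-0.08); the scale is relative, and with library totals every value shifts lower by about the shift in that median.

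Lists of secreted and ER proteins were mostly higher on the TMM scale. Of 25 tested genes for assembly and secretion of very low density lipoprotein (VLDL), 23 were higher and 1 lower, with a median log2 fold change of 1.43 (camera adjusted p = 2.13e-11; adjusted p = 0.123 with an estimated correlation). Apob (ENSMUSG00000020609, chromosome 12, 7977648 to 8016835), the structural protein of VLDL, went from 6669 ± 883 to 16971 ± 4105 CPM, a log2 fold change of 1.35 (SE 0.19, adjusted p = 3.40e-05). Mttp (ENSMUSG00000028158, chromosome 3, 138089854 to 138144968), which loads lipid onto apolipoprotein B, reached 1.60 (SE 0.14, adjusted p = 4.99e-07) and Apoe 1.77 (SE 0.14, adjusted p = 2.12e-07). Of 98 secreted plasma protein genes 92 were higher and 0 lower, with a median of 1.41 (camera adjusted p = 8.20e-26; adjusted p = 0.123 with an estimated correlation), including Alb at 1.32 (SE 0.27, adjusted p = 0.000929) and Serpina3k at 1.52. Of 63 ER chaperone, translocon and glycosylation genes 62 were higher, with a median of 1.45 (camera adjusted p = 6.54e-22; adjusted p = 0.179 with an estimated correlation), among them the chaperones Hspa5 at 1.40 and Hsp90b1 at 1.60 and the translocon-associated Ssr2 at 1.74. Major urinary protein genes were higher in 16 of 18 cases, median 1.68 (camera adjusted p = 5.88e-05; adjusted p = 0.385 with an estimated correlation), with Mup10 at 2.08; reads can be split among these near-identical genes.

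As a share of all counts these lists grew less than their fold changes on the TMM scale. The tests were exact permutations over all assignments, and again with labels exchanged within mice. VLDL genes went from 2.78% ± 0.17 to 3.71% ± 0.28 (SD, n = 6; adjusted p = 0.00354, and 0.0417 within mice; higher in 6 of 6 mice), but from 3.46% to 3.63% of TPM (adjusted p = 0.521). Secreted plasma protein mRNAs went from 17.4% ± 1.4 to 20.6% ± 2.1 of counts, higher in 5 of 6 mice and lower in mouse 4 (adjusted p = 0.0203, but 0.0750 within mice), but from 16.99% to 15.96% of TPM, the opposite direction (adjusted p = 0.521). ER chaperone, translocon and glycosylation genes went from 1.26% to 1.60% and major urinary protein genes from 5.18% to 7.32%, each higher in 6 of 6 mice. They passed within mice (adjusted p = 0.0417 each) but not over all assignments (0.0617 and 0.202). As shares of TPM they were 0.807% and 0.780%, and 9.55% and 10.18% (adjusted p = 0.816 each). Mitochondrially encoded mRNAs themselves rose from 5.47% to 26.34% of TPM, which lowers every other share of TPM. A lower share of TPM therefore need not mean a fall among nuclear mRNAs. Shares of TPM without the mitochondrially encoded genes were not taken. Without mouse 2 the secreted difference in counts was 3.13 points (exact permutation, adjusted p = 0.0595). With mitochondrially encoded genes taken out of the total, the shares went from 2.85% to 4.53% for VLDL genes (ratio 1.588) and from 17.91% to 25.09% for secreted proteins (ratio 1.401; adjusted p = 0.00379 each). These ratios also lie below the median folds of 2.69 and 2.66 on the TMM scale, so the rise in mitochondrial mRNA accounts for only part of the gap.

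Membrane enzymes of drug and lipid metabolism were also higher. Of 53 cytochrome P450 genes 42 were higher and 0 lower, median 1.29 (camera adjusted p = 1.03e-09; adjusted p = 0.123 with an estimated correlation), with Cyp2e1 at 1.28 (SE 0.14, adjusted p = 2.81e-06). Cyp4a14, at 1.44 (SE 1.08), was not called (adjusted p = 0.265) unless the mouse was a block (adjusted p = 9.57e-09). Of 34 UDP-glucuronosyltransferase, flavin monooxygenase and carboxylesterase genes 27 were higher and 1 lower, median 1.43 (camera adjusted p = 2.83e-08; adjusted p = 0.179 with an estimated correlation), including Ces1c at 1.37 and Ces3a at 1.46. Solute carriers outside the mitochondrial family were higher in 138 of 151 cases and lower in 0, median 1.16 (camera adjusted p = 7.09e-23, and 0.123 with an estimated correlation), including Slc38a4, an amino acid transporter, at 1.18. Their share of counts was 0.906% and 0.984% (exact permutation, adjusted p = 0.117). Of TPM it was 0.491% and 0.407%, higher in 0 of 6 mice (adjusted p = 0.0111), with mitochondrially encoded genes in the total. With those genes out of the total, the share of counts rose from 0.9315% to 1.198% (ratio 1.286). It was then higher in 6 of 6 mice (exact permutation, adjusted p = 0.00379).

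Genes of lipid synthesis were split. Of 27 cholesterol synthesis genes 11 were higher, 0 lower and 16 not called, median 1.07 (with the mouse as a block 21 higher and 4 lower; camera adjusted p = 0.0171; adjusted p = 0.628 with an estimated correlation). As a share of counts they were lower in 6 of 6 mice (0.370% and 0.332%; exact permutation, adjusted p = 0.760, and 0.0417 within mice). This direction was lost with mitochondrially encoded genes out of the total. The share was then 0.3802% and 0.4021%, higher in 4 of 6 mice (exact permutation, adjusted p = 0.820). Of 27 fatty acid and triglyceride synthesis genes 14 were higher and 1 lower, median 0.85 (camera adjusted p = 0.00644; adjusted p = 0.385 with an estimated correlation), with the elongase Elovl2 at 1.53 (SE 0.17, adjusted p = 4.63e-06). Bile acid synthesis genes, 8 higher and 2 lower of 16, were not called as a list (camera adjusted p = 0.146).

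mRNAs from the nucleus that encode mitochondrial proteins did not move as one. Of 77 oxidative phosphorylation genes 54 were higher and 4 lower, median 0.58 (camera adjusted p = 1.02e-10, and 0.323 with an estimated correlation). Removing a trend on transcript length moved the camera adjusted p to 0.0485. As a share of counts this list was lower in 6 of 6 mice (1.114% and 0.687%, exact permutation, adjusted p = 0.00354). The share also fell with mitochondrially encoded genes out of the total (ratio 0.729). Cox6a1 was at 1.45 (SE 0.09, adjusted p = 4.74e-08). The ATP synthase genes Atp5b at -0.35 and Atp5a1 at -0.30 were lower, Atp5b changing sign relative to the median with limma on TPM plus 0.1. Mitochondrial ribosomal protein genes were higher in 42 and lower in 4 of 78 cases, median 0.30 (camera adjusted p = 5.02e-05; adjusted p = 0.338 with an estimated correlation and also lost, at 0.339, once a trend on transcript length was removed). Import and chaperone genes were higher in 24 and lower in 2 of 37 cases, median 0.41 (camera adjusted p = 9.65e-05, and 0.126 with an estimated correlation), though the abundant chaperone Hspa9 was lower at -0.44. As shares of counts, mitochondrial ribosomal (0.2345% and 0.1346%) and import genes (0.306% and 0.1605%) were also lower in 6 of 6 mice (exact permutation, adjusted p = 0.00354 each). Not called as lists were fatty acid oxidation (3 higher and 7 lower of 30, median -0.18, camera adjusted p = 0.387), the tricarboxylic acid cycle (2 and 5 of 22, median -0.20, adjusted p = 0.201) and the Slc25 carriers (12 and 5 of 38, median 0.14, adjusted p = 0.201). Removing the length trend turned the first 2 into calls for lower (adjusted p = 0.0485 and 0.0493; with an estimated correlation, the trend left in, 0.797 and 0.628). Of 32 ER-mitochondria contact genes 11 were higher and 9 lower (camera adjusted p = 0.569). Rrbp1, the ribosome-binding protein of the rough ER, was at 1.49 (SE 0.14, adjusted p = 5.68e-07). Its mitochondrial partner Synj2bp was at -0.24 (SE 0.07, adjusted p = 0.0115) and Mfn2 at -0.20 (adjusted p = 0.0770, and 0.00803 with the mouse as a block). Synj2bp lost its call once the length trend was removed. Relative to the median shift, it also did with library totals, the authors' coefficient and limma on TPM plus 0.1.

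The 3 lists called lower in WAM hold genes for nuclear and cytosolic proteins. Of 43 transcription factor and nuclear receptor genes 22 were lower and 4 higher, median -0.45 (camera adjusted p = 0.00142; adjusted p = 0.0812 with an estimated correlation), with Hnf4a at -0.45 (SE 0.08, adjusted p = 0.000396). Nfe2l1, whose protein is inserted in the ER membrane, was higher at 1.13. Of 37 cytoskeletal and cytosolic housekeeping genes 16 were lower and 0 higher, median -0.29 (camera adjusted p = 0.00881; adjusted p = 0.323 with an estimated correlation), including the ferritin chains Fth1 at -1.04 and Ftl1 at -0.74; Actb, at -0.10, was not called (adjusted p = 0.311). Cytosolic glycolysis and gluconeogenesis genes were lower in 9 of 24 cases and higher in 0, median -0.34 (camera adjusted p = 0.0239; adjusted p = 0.126 with an estimated correlation). Cytosolic ribosomal protein genes were higher in 73 of 83 cases, median 0.54 (camera adjusted p = 1.73e-11, but 0.385 with an estimated correlation and 0.261 after removing the length trend). Their share of counts was lower in 6 of 6 mice (1.474% and 0.9645%, exact permutation, adjusted p = 0.00354). It also fell with mitochondrially encoded genes out of the total (ratio 0.779, adjusted p = 0.00631). Urea cycle and amino acid catabolism genes, 4 higher and 13 lower of 29, were not called by camera (adjusted p = 0.0975; 0.564 with an estimated correlation). They were called lower by fry (0.0339), after removing the length trend (0.0374) and with the mouse as a block (0.0156, but 0.584 with an estimated correlation). Cps1, the first enzyme of the urea cycle, was higher at 0.44 (SE 0.11, adjusted p = 0.00344), but negative relative to the median with limma on TPM plus 5. Peroxisomal genes (13 higher and 5 lower of 34, camera adjusted p = 0.255) and proteasome genes (5 and 9 of 37, adjusted p = 0.428; lower at 0.000554 after removing the length trend; 0.838 with an estimated correlation, the trend left in) were not called.

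The lowest log2 fold changes belonged to Spop (ENSMUSG00000057522, chromosome 11, 95414080 to 95493406), a ubiquitin ligase adaptor, which went from 155 ± 8 to 64.6 ± 4.1 CPM (-1.27, SE 0.07, adjusted p = 3.99e-08). It was followed by Zfhx4 at -1.20, Zfyve9 and Pik3c2a at -1.14 each, Nhsl1 at -1.13, Qser1 at -1.10, A1cf at -1.08, Wnk1 and Gprin3 at -1.07 each, and Map3k20 at -1.05. Relative to the median, Zfhx4, Nhsl1, Qser1 and Map3k20 turned positive with limma on TPM plus 5.

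Lysosomal genes were higher in 30 of 30 cases, median 1.51 (camera adjusted p = 4.75e-15; adjusted p = 0.143 with an estimated correlation), including Lamp2 at 1.51, Lamp1 at 1.52 and the protease Ctsd at 1.81. The marker lists of macrophages, endothelial cells and stellate cells were higher as well. Kupffer cell and macrophage markers were higher in 13 of 14 cases, median 1.54 (camera adjusted p = 0.00129; adjusted p = 0.480 with an estimated correlation), with C1qa at 1.86, Cd5l at 1.75 and Clec4f at 1.58. Sinusoidal endothelial markers were higher in 16 of 16 cases, median 1.16 (adjusted p = 3.49e-06; adjusted p = 0.323 with an estimated correlation), and stellate cell markers in 10 of 13, median 1.22 (adjusted p = 0.000433; adjusted p = 0.172 with an estimated correlation). The share of counts from macrophage markers was 0.0435% ± 0.0286 in lysates and 0.0588% ± 0.0370 in WAM (exact permutation, adjusted p = 0.551), and higher in 6 of 6 mice (adjusted p = 0.0417 within mice); of TPM it was 0.0369% and 0.0385% (adjusted p = 0.816). Without mouse 5 the difference was 0.0118 points (exact permutation, adjusted p = 0.0373). The endothelial share was 0.0383% and 0.0362% (exact permutation, adjusted p = 0.573; ratio 0.754 of TPM, adjusted p = 0.0169) and the stellate share 0.0260% and 0.0259% (adjusted p = 0.976). With mitochondrially encoded genes out of the total count, the endothelial ratio was 1.129 (exact permutation, adjusted p = 0.286). The stellate ratio was then 1.183 (adjusted p = 0.00631) and the macrophage ratio 1.632 (adjusted p = 0.358). Mouse 5 stood apart: macrophage markers made up 0.101% of its lysate and 0.134% of its WAM counts, against at most 0.0422% and 0.0533% in the others. Neutrophil markers made up 0.0510% and 0.0600%, against at most 0.000907% and 0.00112%. Saa1, an acute-phase protein, reached 3160 and 12130 CPM, against at most 58.7 and 192. Saa1, at 1.93 (SE 1.73), was not called (adjusted p = 0.356; 1.09e-09 with the mouse as a block). Pericentral hepatocyte genes were higher in 14 of 20 cases, median 1.40 (camera adjusted p = 0.00138, and 0.228 with an estimated correlation). Their share was 1.066% and 1.047% of counts (exact permutation, adjusted p = 0.875) but 0.844% and 0.660% of TPM (adjusted p = 0.0142). The total of TPM includes the mitochondrially encoded mRNAs, whose rise lowers every other share. With those genes out of the total, the pericentral share of counts was 1.096% and 1.268% (exact permutation, adjusted p = 0.124). The periportal list, 7 higher and 6 lower of 15, was not called (camera adjusted p = 0.464), and the difference between these lists was not tested. Erythroid genes, 0 higher and 1 lower of 6, were not called (adjusted p = 0.809). Too few members were tested for lymphocytes (3, 1 higher), nuclear-retained RNAs (2, 0 called), cholangiocytes (2, 1 higher and 1 lower) and neutrophils (1, not called).

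Adjusted over the list alone, the calls higher and lower were 44 and 0 for P450 genes, 29 and 2 for the glucuronosyltransferase list, 9 and 0 for cholesterol synthesis, 9 and 3 for bile acid synthesis and 54 and 5 for oxidative phosphorylation. They were 3 and 4 for fatty acid oxidation, 143 and 0 for solute carriers, 0 and 8 for glycolysis, 2 and 4 for the proteasome, 25 and 3 for import, and 0 and 0 for erythroid genes. For the other lists the counts were those given above. With the mouse as a block, the calls higher and lower were 7 and 15 for fatty acid oxidation, 2 and 13 for the tricarboxylic acid cycle, 18 and 7 for fatty acid and triglyceride synthesis and 9 and 4 for bile acid synthesis. They were 16 and 9 for the Slc25 carriers, 15 and 11 for peroxisomal genes, 6 and 15 for the proteasome, 50 and 7 for mitochondrial ribosomal proteins and 26 and 5 for import. They were 30 and 3 for the glucuronosyltransferase list, 1 and 13 for glycolysis, 3 and 21 for cytoskeletal and housekeeping genes, 11 and 1 for stellate cells, 14 and 1 for pericentral genes, 1 and 0 for neutrophils and 0 and 1 for nuclear-retained RNAs. Cholesterol synthesis aside, the counts of the other lists moved by at most 1.5 times.

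The authors' deposited table of top WAM transcripts holds 205 genes with an enrichment of at least 20% by their measure. It was chosen on these samples and is not independent evidence of direction. All 205 were tested, 200 were called higher, all at least 2-fold, and 0 lower; Cyp4a14, Apoa4, Retsat, Saa2 and Cyp4a10 were not called, and with the mouse as a block 205 were. Scaled to library totals 127 were higher, and with the authors' coefficient 2. The coefficient was applied here to library totals of counts, not to TPM. Most of the list lies below the lysate by the authors' own measure, so this low number follows largely from the division. In the authors' deposited table mt-Co1 ranked highest at 117%, followed by mt-Co3 at 105%, mt-Nd3 at 104%, mt-Co2 at 103% and mt-Cytb at 102%. The 13 mitochondrially encoded genes left aside, the list's median enrichment was 22.5% in the authors' deposited table and its median log2 fold change 1.51. A further 1590 genes at least 2-fold higher lay outside the list. These came from all 11181 tested genes, whereas the authors gave an enrichment value for 1160. Part of the 1590 therefore could not enter the list. Across 1160 genes with a value in the authors' deposited table, enrichment and log2 fold change ranked alike (Spearman rho 0.97, across genes, which are not independent replicates). Retsat, Apoa4, Saa2 and Cyp4a10 are named because they were the exceptions.

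**Figure D3:**
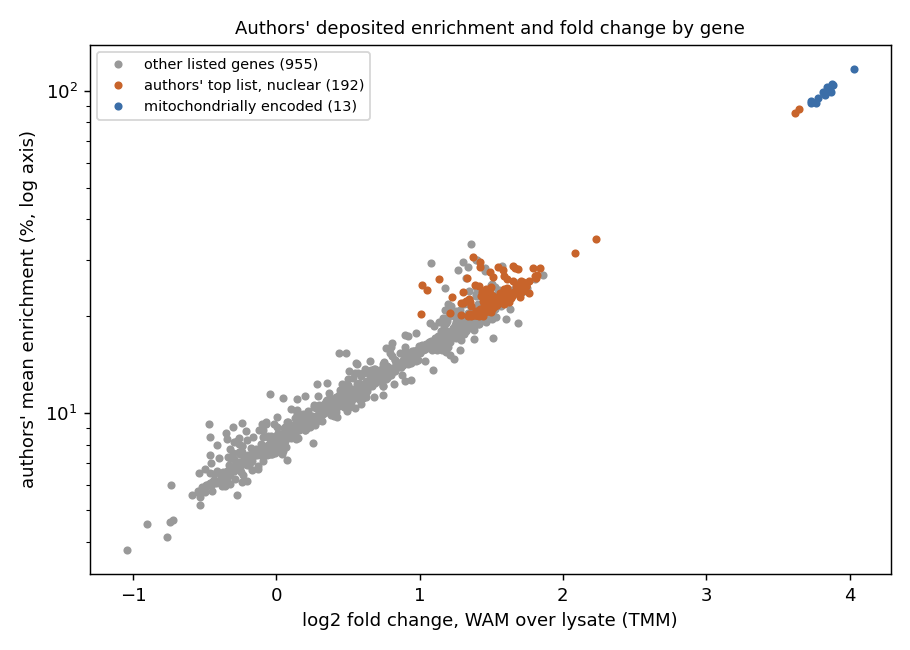
The authors' mean enrichment in percent (y axis, log scale) against the log2 fold change, WAM over lysate on the TMM scale (x axis), for 1160 genes. Blue points are the 13 mitochondrially encoded genes, orange points the nuclear genes of the authors' list of 205, and grey points all others; rho across genes was 0.97, from the same libraries on both axes.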

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

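The grouping of splits by their number of WAM libraries was chosen after the splits were seen, and no other test in this part after its result. The definition of transcript length was corrected after the first length result. The gap ratios below divide the distance from the highest or lowest library to its nearest neighbour by the range of the 6 libraries. They passed Dixon's 95% limit in 24 of 294 groups of libraries (8.16%), where chance gives about 1 in 20.

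Mouse 5 took 16 of these 24 values. Its neutrophil share stood highest in lysate (gap ratio 0.989) and WAM (0.986), as did Saa1 (0.985 and 0.987), the macrophage share (0.783 and 0.837), Cd5l (0.729 and 0.855) and Clec4f (0.656 and 0.825). C1qa (0.785), the sinusoidal endothelial share (0.849), Dcn (0.649) and Ftl1 (0.836) were highest in its WAM library and Cdh5 (0.697) in its lysate, where Slc25a48 was lowest (0.678). No biological explanation for this mouse was tested.

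In mouse 3, Cyp51 was highest in WAM (0.666) and Nhsl1 in lysate (0.640). In mouse 2, mt-Co1 (0.634; 6915 CPM against 3825 to 4958) and Lamp1 (0.667) were highest in lysate, the share of nuclear-retained RNAs was highest in WAM (0.642), and Hsp90b1 lowest in WAM (0.665). Lysate 6 had the highest total count (0.783), and WAM library 6 the highest share of fatty acid oxidation genes (0.659; 0.657% against 0.344% to 0.450%).

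Of the genes at a log2 fold change of 2 or more and at least 10 CPM, 13 were not in the mitochondrial genome. Of these, 7 (53.85%) share a 31-base word with a mitochondrially encoded transcript, against 1 of 11155 other genes (0.00896%), so reads shared with mitochondrial transcripts are a candidate explanation. It is weaker for Cep295 (3.54), which shares 4 of 6124 words, and Gm20594 (3.65), which shares 42 of 419. The other 5, among them Gm28437 (4.21) and Gm28438 (4.08), which lie above mt-Co1 (4.03), share nearly all of theirs, at the least Gm29216 with 449 of 462. Nudt14 (3.62), Lars2 (2.23), Gm12895 and Gm12896 (2.20 each, with identical counts), Mup10 and Gm20388 (2.03) share no such word and stay open. These genes other than Mup10 were picked out after their values were seen.

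Long mRNAs were lower in WAM, with a Spearman rho of -0.35 between log2 fold change and transcript length across all tested nuclear genes. Within secreted, lysosomal and ER genes rho was -0.1437 (95% interval -0.281 to -0.00139), and within secreted and ER genes alone -0.1658, with an interval that included 0 (-0.320 to 0.00713). Across transcription factor and cytosolic genes it was -0.452, so loss of long transcripts in WAM libraries may contribute. With length taken from the longest transcript, the value for secreted, lysosomal and ER genes was -0.129, and its interval also included 0 (-0.268 to 0.0142). A fit on length left 90.13% of the gap between secreted and transcription factor medians (1.86 before, 1.68 after), which goes with the class of the encoded protein and leaves little of this gap to length. Both explanations stay open for the trend over all genes, and genes are not independent replicates.

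Macrophage markers had a median log2 fold change of 1.54 (95% interval 1.38 to 1.72). More macrophage RNA of every kind in WAM would raise all leukocyte mRNAs. A rise limited to ER-bound macrophage mRNA need not raise those for cytosolic or nuclear proteins. The 26 leukocyte genes for cytosolic or nuclear proteins had a median of -0.02 (interval -0.159 to 0.118, 1 higher, 1 lower). Most were under 10 CPM. A rise as large as that of the markers was not seen in these genes. Their median still lay above those of the cytosolic housekeeping (-0.29) and transcription factor (-0.45) lists. A smaller rise in macrophage RNA is therefore not ruled out, and these genes cannot show a rise limited to ER-bound macrophage mRNA. The markers lay 0.1276 above the secreted plasma protein median, so the class of the encoded protein (secreted, lysosomal or membrane) stays open as a hypothesis: ER-bound mRNAs of these cells may be recovered with WAM.

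The 12 libraries can be split into 6 and 6 in 462 ways, of which 100 were run, the real split included. For called genes, 1 of 100 splits, the real one, gave as many (6511, highest other 0 with edgeR, the one tool run on splits). At unadjusted p under 0.05 the real split gave 7014 genes against at most 3875. For 2-fold genes it was again 1 of 100 (1861, highest other 0). Because every other split mixes the fractions, these counts cannot exclude chance. Nor can those for gene lists: 21 of 100 splits, the real one included, gave at least the real 22, and the highest other gave 25. Splits with unequal numbers of WAM libraries keep part of the difference between fractions: 4 of 6 with 1 WAM library in a group and 15 of 55 with 2 gave as many. Of 38 others with 3 WAM libraries in each group, 1 did, but they called 2 to 23 lists (median 8), so the preset correlation calls lists without that difference. Among the drawn splits, 7 others also part all 6 pairs of libraries; they put at least 1 WAM library in each group, and called 0 genes but up to 25 lists; with the real one these are too few to judge chance by. Every other split mixes the fractions within its groups, which widens their spread and lowers the number of genes they can call.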

How the results depend on the processing

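Median-centred limma, the length trends, leaving out genes that share a word with mitochondrial transcripts, leaving out mouse 2 or mouse 5, the block with an estimated correlation, and exchanging labels within mice were chosen after seeing the data. The counts 3293 higher, 3218 lower, 1790 at least 2-fold higher and 71 at least 2-fold lower stayed within 1.5 times with DESeq2 (3283, 2968, 1824 and 68), DESeq2 size factors (3375, 3084, 1846 and 66), TMM without abundant genes, without word-sharing genes, without mouse 2 (3204, 3082, 1901 and 83) and without mouse 5 (3254, 2940, 1705 and 90). With the replicate block they were 3747, 4044, 1846 and 79. Besides the genes named next, the 5 genes of the authors' list and the urea cycle list (19 lists higher, 4 lower), whose calls it added, the block changed no other call of a gene given here or of a list as a whole. It did change counts of called members within lists. The genes were Saa1, Cyp4a14, Acaa2, Pcx, Slc25a15, Slc25a47, Bhmt, Mat1a, Hspd1 and Mfn2. Library totals gave 503, 8652, 27 and 6720, and 127 and 16 of the authors' list higher and at least 2-fold higher. The authors' coefficient gave 6, 11152, 1 and 11152, with 2 and 0. Limma gave 56, 9570, 23 and 6902 at TPM plus 1. It gave 55, 9569, 24 and 8130 at plus 0.1, and 56, 9565, 20 and 3587 at plus 5, each with 26 and 15 of the authors' list. The coefficient divides every WAM value, so by construction it lowers the typical mRNA; with totals the rise in mitochondrial mRNA is part of the cause, and no other cause was tested. Median-centred limma gave 4130, 2434 and, at least 2-fold lower, 22.

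Genes at least 2-fold lower numbered 188 without a filter, 33 with at least 5 TPM in lysates and 37 over the 12 libraries, since other genes were tested. Leaving out single libraries gave 3135 to 3304 higher, 2974 to 3153 lower, 1634 to 1899 at least 2-fold higher, and 198 to 201 of the authors' list. Genes at least 2-fold lower then ranged from 74 to 1.2e+02, the highest without WAM library 5. The 19 and 3 list calls fell to 0 and 0 with an estimated correlation, and to 0 and 0 with the replicate block added to it; fry gave 24 and 4, adding the bile acid, Slc25 carrier, peroxisome, ER-mitochondria contact and periportal lists as higher and the urea cycle list as lower. Removing the length trend gave 17 and 7 lists, with either length definition. Relative to the median shift, named genes changed sign with TPM plus 1 (Mrps7 -0.0009, Psmd2 0.015) and plus 0.1 (Atp5b 0.0746, Psmd2 0.1701). They also did with plus 5 (Zfhx4 0.2779, Nhsl1 0.2492, Qser1 0.0025, Map3k20 0.1106, Mrpl12 -0.1621, Mrps7 -0.2339, Cps1 -0.1218), centring (Mrps7 -0.0251) and the length trend by longest transcript (Mrpl12 -0.0237). Without the shift taken off, 14 of 93 called named genes changed sign with library totals, 58 with the authors' coefficient and 40 with TPM plus 1. With the replicate block as an exchange of labels within mice, the mitochondrial share still differed by 15.24 points (adjusted p = 0.0417). The secreted share lost its call (0.0750). The ER chaperone, major urinary protein and macrophage shares gained one as higher (0.0417 each). The cholesterol synthesis share gained one as lower (0.0417), with mitochondrially encoded genes in the total. No other share given here changed its call. The secreted share differed by 3.17 points of counts but -1.029 points of TPM. The mitochondrial share of TPM differed by 20.87 points, which lowers every other share of TPM. The cause was not tested for any change not explained above. Testing transcripts without summing was not run, as the table is by gene. In the simulated data 58.2% of 1.5-fold changes were recovered, so small changes can be missed at this depth.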

Other observations

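Grouped by the authors' marks of protein localisation, a use chosen after the marks were seen, tested nuclear genes fell into levels. Median log2 fold changes were 1.42 for 132 genes of the extracellular space, 1.41 for 83 lysosomal, 1.38 for 270 ER and 1.28 for 133 Golgi, endosome and plasma membrane genes. They were 0.54 for 66 ribosomal, 0.38 for 249 mitochondrial, 0.04 for 99 nuclear, -0.02 for 10 cytoskeletal, -0.03 for 8 peroxisomal and -0.08 for 64 cytosolic genes. With 7 lipid droplet genes the median was 0.59, and with 26 others 0.53. Of the genes marked nuclear 30 were called higher and 17 lower, and of those marked cytosolic 18 and 12. The marks cover genes with at least 5 TPM after division by the coefficient in 6 WAM libraries, per the file headers, a choice that favours genes high in WAM. These values describe the genes of the authors' table and were not tested against each other.

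The authors' coefficient was 5.02, 2.84, 5.07, 5.72, 6.40 and 4.16 in mice 1 to 6 (mean 4.87, SD 1.25), and the same values were obtained from the TPM.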
